A study of Mus musculus with 18 samples.

How the data were processed

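Gene expression was measured on Affymetrix arrays in mouse bone marrow-derived macrophages, cells grown out of femoral marrow with the growth factor M-CSF at 30 ng/mL. Per the labels' protocols, the medium was replaced after 4 days by medium with 10% plasma from mice fed a Western diet for 8 weeks, and RNA was isolated 48 hours later, on day 6. The plasma came from wild-type C57BL/6J mice (WT), from mice without apolipoprotein E (ApoE), or from mice without apolipoprotein E and without stabilin-1 (AS1) or stabilin-2 (AS2). The labels name the knockouts for the plasma donors, so Apoe, Stab1 and Stab2 levels in the macrophages do not check the labels. RNA was extracted with a kit for microRNA isolation, and biotin-labelled cRNA was hybridised, per the labels' protocols.

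The deposited values are log2 expression values from RMA (robust multi-array average, which corrects background, equalises the distributions of arrays and summarises probes), per the submitters' processing notes; the RMA version and the probe set definition are not given in the sources used here. The deposited table held 25428 rows for 18 arrays. The sorted values of 17 arrays were the same, and those of ApoE replicate 1 differed from them by at most 0.0019. ApoE replicate 1 held 24162 distinct values, against 7087 in each of the 17 others. Whether it was processed differently is not given in the sources used here. Because the distributions were made equal, a change in total RNA per cell cannot be seen. The platform annotation gave 24705 rows exactly 1 gene symbol and 0 rows several; 723 rows were not listed there and are unnamed here. Arrays have no read depth, and their number limits the precision: 4 WT, 5 ApoE, 3 AS1 and 6 AS2 arrays. The labels do not say whether replicates were separate cultures or plasma donors, so p-values measure only the spread between these arrays, which may be technical. No array batch was named in the labels.

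From the deposited log2 values, limma 3.58.1 in R 4.3.3 fitted 1 linear model with 4 group means to the 24705 rows (lmFit and eBayes, 14 residual degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment over rows and a threshold of 0.05. The 3 main comparisons were ApoE against WT, AS1 against ApoE and AS2 against ApoE, and the other pairs of groups were tested in the same model. For gene lists, 1 row per gene was used. Camera tested 30 lists, 19 of pathways and 11 of cell type markers, with a preset inter-gene correlation of 0.01 and adjustment over 90 tests; camera with an estimated correlation and fry were run beside it. Of 492 list genes, 460 were measured. List genes that the annotation holds under an older symbol were matched by that symbol.

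The groups, lists, tests of the comparisons, naming rule and alternatives were fixed before the data were examined, except an added fit and some tests of explanations in the closing section, which are named where they are given. The rule named, in each main comparison, the 10 largest changes past the threshold in each direction, passing over predicted genes, small RNA genes and pseudogenes. It also named up to 4 members with the smallest p from each list that was called or had at least 3 members past the threshold, up to 2 from other lists, and 8 fixed genes, of which 6 had a row. The text prints part of the list members so named. In the other comparisons the rule named 3 genes per direction.

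Comparisons that share the ApoE arrays have correlated chance values. Their correlation and covariance across rows were therefore set beside 100 simulated data sets of unchanged groups, made by moving residuals between arrays, and recomputed with the ApoE arrays divided in 2 parts in 20 ways. Genes are not independent replicates in these correlations.

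Scripts were tested on simulated data with the real row means and spreads. For ApoE against WT over 24705 rows, 82 of 100 rows changed by 0.5 log2 units were called, 49 of 50 changed by 1, and 50 of 50 changed by 2. Of the calls, 7.18% were rows left unchanged. Camera called the shifted list and 0 of 89 unshifted tests, and a shared covariance of 0.01 was recovered as 0.00982. The simulated genes were independent of each other, whereas the real ER stress and neutrophil lists had estimated correlations of 0.34 and 0.68. The 0 of 89 therefore does not show how often camera calls unshifted lists in these data.

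Alternatives were all rows of the table, a filter at the 40th percentile of row means, 1 row per gene, renewed quantile normalization, median centring, a trended robust variance, array weights, the 2 compared groups alone, the replicate number as a block, and each array left out. A fit without ApoE replicates 2 and 5 was added after the data were seen. Genome coordinates were not used here.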

Results

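The series measured 18 arrays of mouse bone marrow-derived macrophages after 48 hours with plasma of Western diet-fed mice: 4 with WT plasma, 5 with ApoE plasma, 3 with AS1 plasma and 6 with AS2 plasma. ApoE plasma came from mice without apolipoprotein E, a carrier of plasma lipids, and AS1 and AS2 plasma from mice that also lacked stabilin-1 or stabilin-2, which are scavenger receptors. The median array value was 4.37 on the log2 scale. Arrays of a group correlated with each other at a mean r from 0.9912 to 0.9971 across genes, which are not independent replicates. The lowest value belonged to ApoE replicate 2. ApoE replicate 5 had AS1 replicate 3 as its closest array of another group, at r = 0.9935.

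**Figure D1:**
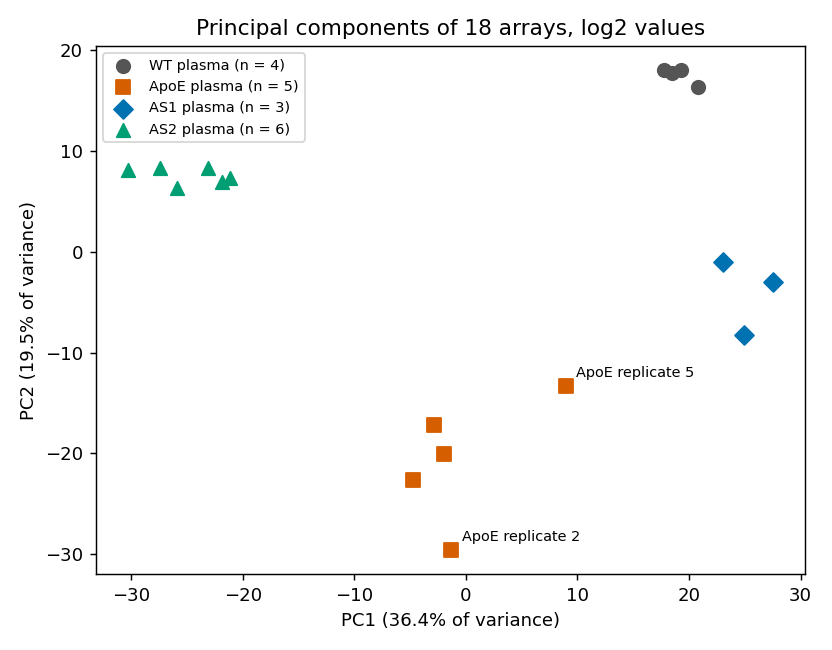
Each point is 1 array, placed by the first (PC1) and second (PC2) principal component of the log2 values, in arbitrary units, with colour and shape giving the plasma. PC1 held 36.4% of the variance and PC2 19.5%; the 4 plasma groups lay apart, and ApoE replicate 5, at 8.94 on PC1, lay between the other ApoE arrays (-4.79 to -1.30) and both the WT (17.7 to 20.8) and the AS1 arrays (23.1 to 27.5).

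The comparison of ApoE with WT plasma asks what plasma of hyperlipidaemic mice does to macrophage expression. With ApoE plasma, 21 of 22 genes of the ER stress and amino acid response list and 29 of 33 proliferation genes rose (camera adjusted p = 2.37e-29 and 7.75e-39). With an estimated correlation these lists had camera adjusted p = 0.00691 and 0.00241. Asns, asparagine synthetase, was 9.70 ± 0.42 (SD, n = 5) against 6.10 ± 0.30 (SD, n = 4) in log2 values, a 12.1-fold difference. The mitochondrial folate enzyme gene Mthfd2 rose by 3.37 ± 0.16 (SE) log2 units and the amino acid transporter genes Slc7a5 and Slc7a1 by 3.35 ± 0.19 and 2.52 ± 0.21. Among the genes that fell, Cd300e was 4.94 ± 0.13 against 8.64 ± 0.15, 3.70 log2 units lower, and the scavenger receptor gene Marco was 6.03 ± 0.45 against 9.16 ± 0.08. Of 24705 rows tested, 2111 rose and 2066 fell, and 335 of these 4177 rows changed at least 2-fold.

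Among the 10 largest increases were also the coagulation factor gene F5 (3.04), the division genes Prc1 (2.58), Ccna2 (2.42), Anln (2.41) and Ect2 (2.18), and Cd200r4 (2.26), all in log2 units. The largest decreases included Fcrls (-2.94), Adgre4 (-2.26), the transcriptional inhibitor gene Id3 (-2.19), Tmem176a (-2.17), the lectin genes Clec4a2 (-2.14) and Clec4b1 (-2.13), Cbr2 (-2.10) and Slc13a3 (-2.06). The ApoE and WT arrays did not overlap in 14.3% of all rows, where chance gives 1.59%.

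Camera called 15 of 30 lists. In the proliferation list, 29 of 33 measured genes rose and 4 did not pass (30 rose adjusted over the list alone), with a median change of 0.93 log2 units and camera adjusted p = 7.75e-39. Mki67, a marker of cycling cells, rose by 2.13 ± 0.07, and Tpx2 and Ccnb2 by 1.86 and 2.18. In the list of ER stress and amino acid response genes, 21 of 22 rose (21 adjusted over the list alone, median 0.99, adjusted p = 2.37e-29). The transcription factor genes Atf4 and Ddit3 rose by 1.48 and 1.86, and the chaperone gene Hspa5 by 1.02.

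Of 28 interferon-stimulated genes, 15 fell and 13 did not pass (18 fell adjusted over the list alone, median -0.33, adjusted p = 8.34e-10), among them Irf7 (-1.59), Oasl2 (-0.91) and Oas2 (-0.82). Of 23 NF-kB and cytokine genes, 12 fell, 1 rose and 10 did not pass (13 and 2 adjusted over the list alone, adjusted p = 2.22e-07). Nfkbiz and the anti-inflammatory cytokine gene Il10 fell by 1.01 and 1.14, whereas Il1a rose by 1.68. Of 16 NRF2 target genes, which act against oxidative stress, 8 fell, 1 rose and 7 did not pass (10 and 1 adjusted over the list alone, adjusted p = 1.90e-06), with Nqo1 at -1.79 and Gclm at -0.95. Of 23 adhesion genes, 15 fell, 2 rose and 6 did not pass (18 and 2 adjusted over the list alone, adjusted p = 3.12e-08); Itgal and Coro1a fell by 1.64 and 1.11 and Itgb3 rose by 1.74. Of 10 macrophage markers, 7 fell, 1 rose and 2 did not pass (7 and 1 adjusted over the list alone, median -0.44, adjusted p = 4.02e-05), including Aif1 (-1.42) and the M-CSF receptor gene Csf1r (-0.39).

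Lipid handling genes moved both ways. Of 15 LXR targets, the sterol-responsive genes of cholesterol efflux, 6 rose, 1 fell and 8 did not pass (6 and 2 adjusted over the list alone, adjusted p = 0.000286, and adjusted p = 0.0673 with an estimated correlation). The exporter genes Abcg1 and Abca1 rose by 1.06 ± 0.049 and 0.93 ± 0.06. Of 21 cholesterol synthesis genes, 5 fell and 16 did not pass (5 adjusted over the list alone, adjusted p = 0.0231, and adjusted p = 0.27 with an estimated correlation), and the call was lost without WT replicate 1, ApoE replicate 2 or ApoE replicate 5 (adjusted p = 0.0598, 0.152 and 0.0674). It was also lost without both ApoE replicates 2 and 5 (adjusted p = 0.438), with array weights (0.0819) and with rows of low mean left out (0.0745). Of 25 lysosomal genes, 12 rose, 4 fell and 9 did not pass (14 and 5 adjusted over the list alone, adjusted p = 5.20e-05), with Atp6v0d2 at 1.18 and the cholesterol transporter gene Npc1 at 0.79. In the list of PPAR targets, which was not called (adjusted p = 0.0958), 7 of 18 rose and 3 fell (7 and 4 adjusted over the list alone); Fabp5 rose by 2.05 and the lipase gene Lpl fell by 0.79.

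A further 5 lists were called with the preset correlation alone. Of 14 complement and Fc receptor genes 10 fell (12 adjusted over the list alone, adjusted p = 1.71e-08, and adjusted p = 0.0625 with an estimated correlation), with Fcgr1 at -0.72 and C1qa at -1.14. Of 13 MHC class II genes 9 fell and 1 rose (9 and 3 adjusted over the list alone, adjusted p = 0.000663, and adjusted p = 0.15 with an estimated correlation), with H2-Eb1 at -1.23. Of 22 scavenger receptors 8 fell and 1 rose (8 and 3 adjusted over the list alone, adjusted p = 0.0352, and adjusted p = 0.261 with an estimated correlation), with Scarb1 at -1.03. The scavenger receptor call was lost without WT replicate 2, ApoE replicate 3 or ApoE replicate 4 (adjusted p = 0.105, 0.0686 and 0.0572). Of 6 megakaryocyte and platelet markers 5 rose and 1 fell (5 and 1 adjusted over the list alone, adjusted p = 0.00168, and adjusted p = 0.135 with an estimated correlation), with Itga2b at 1.46. Of 8 dendritic cell markers 5 rose (5 adjusted over the list alone, adjusted p = 0.0153, and adjusted p = 0.117 with an estimated correlation), from a median WT level of 4.22. With rows of low mean left out, the scavenger receptor and dendritic cell calls were lost (adjusted p = 0.0824 and 0.1).

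The other lists were not called. Neutrophil markers had 2 higher, 1 lower and 10 not past of 13 (4 and 1 adjusted over the list alone, adjusted p = 0.0606), with Mpo at 0.81. This list passed in 5 of 26 alternative settings (lowest camera adjusted p = 0.00226). Chemokine genes had 7 higher and 8 lower of 25 (9 and 8 adjusted over the list alone, adjusted p = 0.758): the receptor gene Ccr2 fell by 1.84 and Ccrl2 rose by 1.64. Immediate early genes had 5 higher and 6 lower of 25 (5 and 6 adjusted over the list alone, adjusted p = 0.847); Fos and Junb fell by 0.73 and 0.62, and Egr1 was 5.65 against 5.69 (adjusted p = 0.95). Fatty acid synthesis (5 higher, 3 lower of 16), glycolysis and hypoxia (6 and 2 of 20, with Vegfa at 1.87), matrix remodelling (4 and 4 of 20) and alternative activation (1 and 2 of 18) had adjusted p from 0.268 to 0.613. In the same order, 5 and 3, 6 and 2, 6 and 4, and 2 and 2 genes passed adjusted over the list alone. Markers of B cells, T and NK cells, erythroid cells, mast cells with basophils and eosinophils, osteoclasts, stromal and endothelial cells had adjusted p from 0.368 to 0.848. The chemokine, immediate early, glycolysis, B cell and osteoclast lists had a median, mean and test that differed in sign. Of 100 divisions of these 9 arrays into groups of 4 and 5, 8 gave 15 or more called lists, the real one included, so chance was not excluded for this number.

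**Figure D2:**
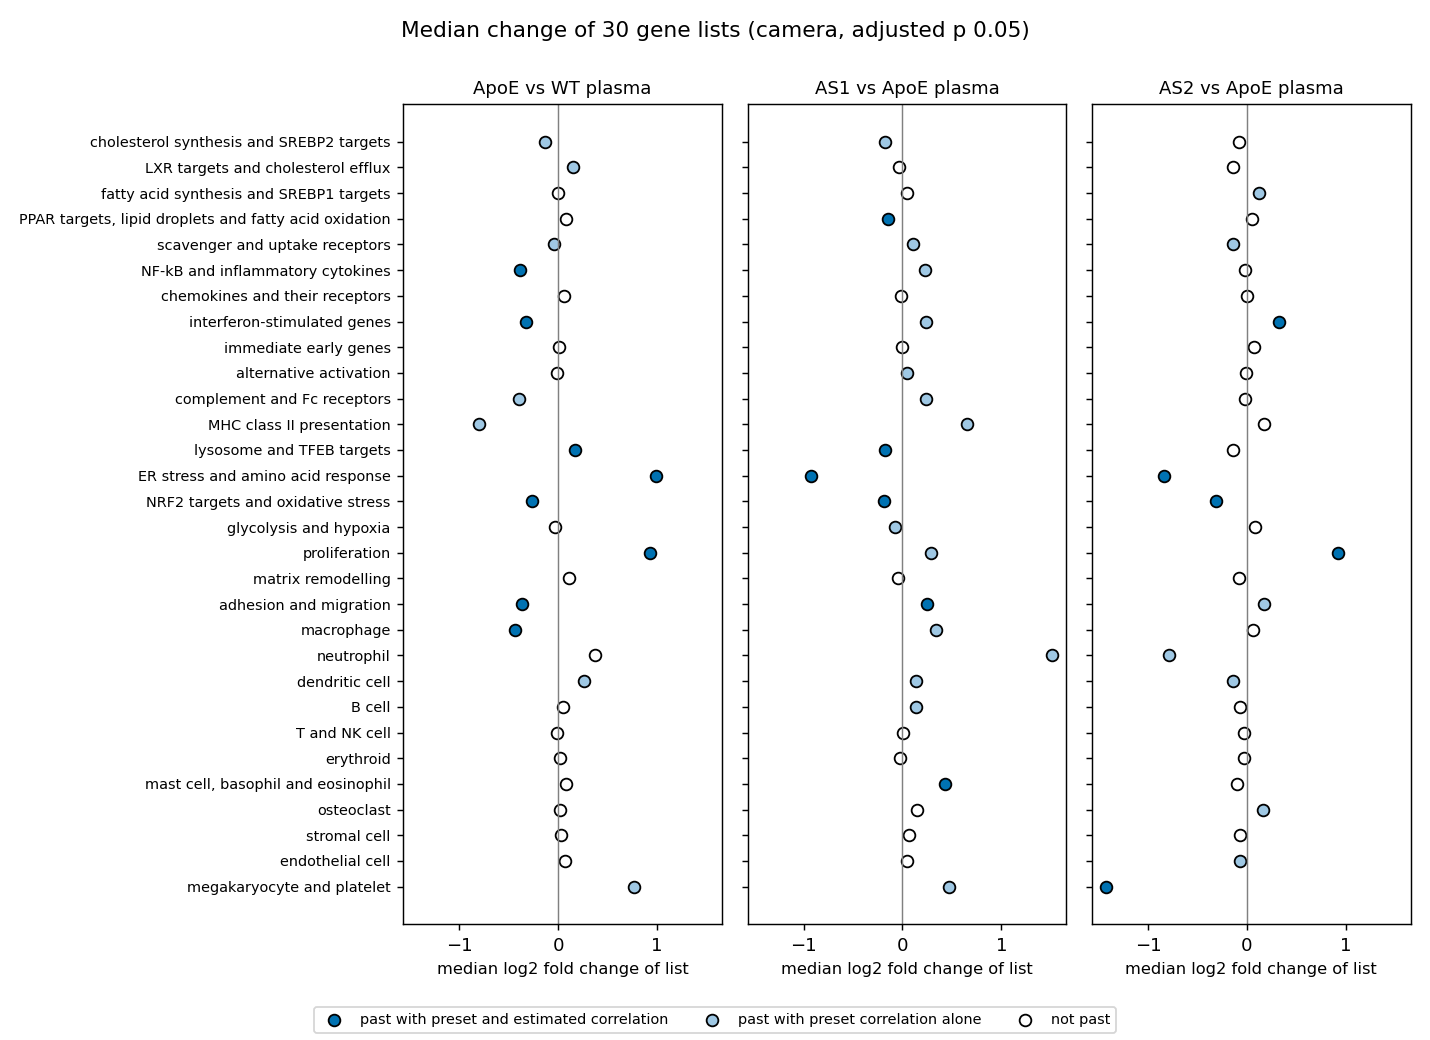
Median log2 fold change of each of 30 gene lists (horizontal axis) in the 3 main comparisons. Dark points passed the camera test with preset and estimated correlation, light points with the preset correlation alone, and open points did not pass. The ER stress and amino acid list lay at 0.99, -0.93 and -0.84.

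AS1 was compared with ApoE plasma to show what changes when the plasma donors also lacked stabilin-1. With AS1 plasma, all 13 neutrophil markers rose, as a list with camera adjusted p = 5.01e-13 and adjusted p = 0.0652 with an estimated correlation. Prtn3 and Mpo, 2 enzymes of early granules, were 9.62 ± 0.34 and 10.26 ± 0.21 (SD, n = 3) against 7.35 ± 0.59 and 8.47 ± 0.50 (SD, n = 5). The cytokine gene Il1b rose by 2.07 ± 0.20 (SE) log2 units. Fcrls, Marco, Tmem176a and Adgre4, which were lower with ApoE than with WT plasma, rose by 3.23, 2.68, 2.45 and 2.02. The amino acid genes Asns, Slc7a1 and Mthfd2 fell by 2.10, 1.79 and 1.65. Of 24705 rows, 1913 rose and 2175 fell, and 266 changed at least 2-fold.

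The largest increase, of Slc13a3 (3.25 ± 0.41), came with an SD of 1.57 within AS1. Stfa2l1 (2.38), Il1f9 (2.23) and Tmem176b (1.97) were among the 10 largest. The largest decreases included Cd200r4 (-2.14), Bhlhe41 (-1.91), the stress gene Nupr1 (-1.91), the endothelial growth factor receptor gene Kdr (-1.74), Rai14 (-1.72), Lrp12 (-1.68) and the fatty acid-binding protein gene Fabp5 (-1.66). The AS1 and ApoE arrays did not overlap in 18.2% of all rows, where chance gives 3.57%. Egr1 was 4.59 ± 0.18 against 5.65 ± 0.52 and fell (adjusted p = 0.00244).

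Camera called 20 lists, and 6 of them also with an estimated correlation. In the ER stress and amino acid list 19 of 22 genes fell and 3 did not pass (19 adjusted over the list alone, median -0.93, adjusted p = 1.25e-23, and adjusted p = 0.0123 with an estimated correlation), including Ddit3 (-1.51), Pdia6 (-1.14) and Hspa5 (-0.94). Of 25 lysosomal genes 13 fell and 2 rose (16 and 3 adjusted over the list alone, adjusted p = 5.77e-08), with Sqstm1 at -0.97 and Npc1 at -0.66. Of 18 PPAR targets 7 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.00688), with the lipid droplet gene Plin2 at -0.36 (the exception was Lpl, 0.33). Of 16 NRF2 targets 6 fell and 2 rose (7 and 2 adjusted over the list alone, adjusted p = 0.00834), with Slc7a11 at -1.25. Of 23 adhesion genes 10 rose and 2 fell (12 and 2 adjusted over the list alone, adjusted p = 1.21e-06), with Itgal at 1.91. Of 9 mast cell, basophil and eosinophil markers 5 rose (5 adjusted over the list alone, adjusted p = 4.43e-05), with Prg2 at 1.89 and Cpa3 at 1.47.

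All 13 neutrophil markers rose (13 adjusted over the list alone, median 1.51, adjusted p = 5.01e-13, and adjusted p = 0.0652 with an estimated correlation). Elane, an early granule protease gene, rose by 1.81 and Mpo by 1.79. In the same arrays 7 of 10 macrophage markers rose and 1 fell (7 and 2 adjusted over the list alone, median 0.34, adjusted p = 0.000808, and adjusted p = 0.0612 with an estimated correlation), among them Adgre1 (0.46) and Csf1r (0.35). Interferon-stimulated genes had 9 of 28 higher (13 adjusted over the list alone, adjusted p = 4.13e-06, and adjusted p = 0.0645 with an estimated correlation), with Oas2 at 0.63. Of 13 MHC class II genes 6 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 3.25e-05, and adjusted p = 0.0791 with an estimated correlation), with the class II transactivator gene Ciita at 1.63. Of 14 complement genes 7 rose (9 adjusted over the list alone, adjusted p = 2.93e-06, and adjusted p = 0.112 with an estimated correlation), with C1qa at 0.74 (adjusted p = 0.0539 in a fit of the 2 groups alone). Of 23 NF-kB genes 10 rose and 3 fell (12 and 3 adjusted over the list alone, adjusted p = 0.00308, and adjusted p = 0.0645 with an estimated correlation). Of 33 proliferation genes 10 rose and 1 fell (13 and 1 adjusted over the list alone, adjusted p = 0.000174, and adjusted p = 0.233 with an estimated correlation), with Mki67 at 0.39.

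Cholesterol synthesis genes had 5 of 21 lower (5 adjusted over the list alone, adjusted p = 0.0158, and adjusted p = 0.24 with an estimated correlation), with Hmgcs1 at -0.71. Glycolysis and hypoxia genes had 7 of 20 lower and 1 higher (7 and 2 adjusted over the list alone, adjusted p = 0.0199, and adjusted p = 0.295 with an estimated correlation), with Ldha at -0.63, and the call was lost with the replicate number as a block (adjusted p = 0.0558). Scavenger receptors had 8 of 22 higher and 2 lower (10 and 4 adjusted over the list alone, adjusted p = 0.0289, and adjusted p = 0.24 with an estimated correlation); Msr1 fell by 1.06, and the call was lost without ApoE replicate 4 or AS1 replicate 3 (adjusted p = 0.0554 and 0.0699). Alternative activation genes had 4 of 18 higher and 1 lower (4 and 1 adjusted over the list alone, adjusted p = 0.0295, and adjusted p = 0.135 with an estimated correlation), with Chil3 at 1.06, and the call was lost without ApoE replicate 1 or AS1 replicate 2 (adjusted p = 0.0544 and 0.0656). The megakaryocyte (3 of 6 higher), dendritic cell (2 of 8) and B cell lists (2 of 6) were called with adjusted p = 0.0199, 0.0295 and 0.0199. With an estimated correlation, these lists had adjusted p = 0.24, 0.164 and 0.233. The dendritic cell call was lost without ApoE replicate 1 or AS1 replicate 1 (adjusted p = 0.0702 and 0.0594), and the B cell call without AS1 replicate 1 (adjusted p = 0.0967). With rows of low mean left out, the cholesterol synthesis, scavenger receptor, megakaryocyte, dendritic cell and B cell calls were lost (adjusted p = 0.054, 0.0748, 0.0546, 0.115 and 0.269). LXR targets (1 higher, 1 lower of 15), fatty acid synthesis (2 and 4 of 16), chemokines (5 and 3 of 25), immediate early genes (2 and 7 of 25), matrix remodelling (5 and 5 of 20) and the T and NK cell, erythroid, osteoclast, stromal and endothelial lists were not called, with adjusted p from 0.0588 to 0.976. For the first 5 of these, 1 and 1, 3 and 4, 6 and 4, 3 and 7, and 5 and 7 genes passed adjusted over the list alone. The LXR, fatty acid synthesis, chemokine, matrix, erythroid and endothelial lists had a median, mean and test that differed in sign. Abca1 was 11.75 against 11.80 (adjusted p = 0.732). Stab1 and Stab2 of the macrophages were 11.97 and 5.85 against 11.83 and 5.48 (adjusted p = 0.134 and 0.155).

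The 126 rows of small nucleolar and other small RNAs moved with these changes: 50 fell and 1 rose, with a median of -0.40 log2 units. Without ApoE replicates 2 and 5, a choice made after the data were seen, 4398 rows changed rather than 4088.

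**Figure D3:**
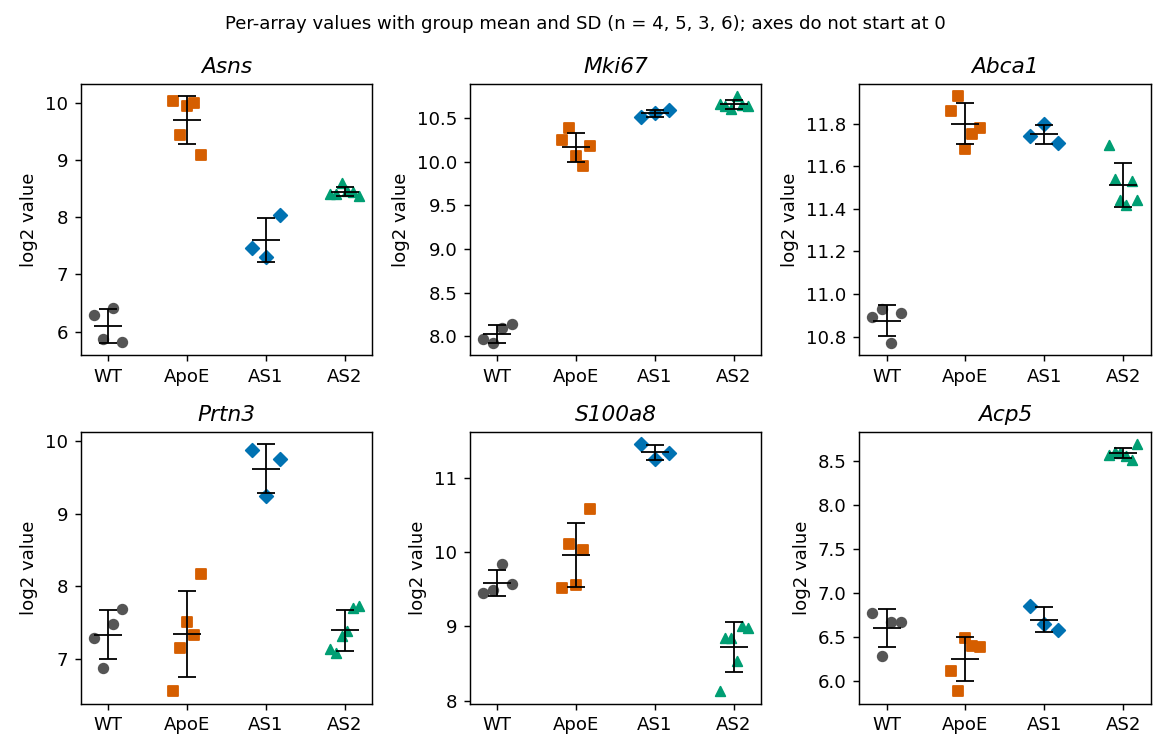
Log2 values of 6 genes in each array by plasma, with the group mean and SD as a bar and whiskers (n = 4 WT, 5 ApoE, 3 AS1 and 6 AS2). Asns averaged 6.10 with WT, 9.70 with ApoE and 7.60 with AS1 plasma; Prtn3 was higher in the AS1 arrays, and Acp5 in the AS2 arrays, than in the ApoE arrays.

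AS2 was compared with ApoE plasma to show what changes when the donors also lacked stabilin-2. With AS2 plasma, all 33 proliferation genes rose and 21 of 22 genes of the ER stress and amino acid list fell (camera adjusted p = 2.95e-44 and 3.02e-26). With an estimated correlation these lists had camera adjusted p = 0.00241 and 0.00984. Acp5, tartrate-resistant acid phosphatase, was 8.58 ± 0.06 (SD, n = 6) against 6.26 ± 0.25 (SD, n = 5), and the fusion gene Dcstamp rose by 2.43 ± 0.17 (SE) log2 units. The protocadherin gene Pcdh7 was 9.18 ± 0.11 against 6.03 ± 0.23, 8.88-fold higher. The integrin gene Itgax, the protease gene Plau and the interleukin-1 antagonist gene Il1rn rose by 2.87, 2.20 and 2.05. F5 was 5.82 ± 0.20 against 8.92 ± 0.27, 8.58-fold lower, and the matrix glycoprotein gene Thbs1 fell by 2.51 ± 0.12. Of 24705 rows, 1876 rose and 1981 fell, and 300 changed at least 2-fold.

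Emp2 (2.88), Slco4a1 (2.41), Ptchd1 (2.11) and Flrt2 (2.02) completed the 10 largest increases. The largest decreases included the cystine transporter gene Slc7a11 (-2.35), the lectin genes Clec4n (-2.26) and Clec4e (-2.14), the iron exporter gene Slc40a1 (-2.16), Ccrl2 (-2.10), the flagellin receptor gene Tlr5 (-2.08), Pde7b (-1.98) and Stat4 (-1.97). The AS2 and ApoE arrays did not overlap in 10.9% of all rows, where chance gives 0.433%. Stab1, Apoe and Stab2 of the macrophages themselves fell by 0.79, 0.36 and 0.46 (adjusted p = 3.39e-09, 0.00114 and 0.0268). The Stab2 call was lost under 6 alternatives that leave out arrays (ApoE replicate 1 or 5, both ApoE replicates 2 and 5, or AS2 replicate 3, 4 or 5), with an adjusted p up to 0.0866.

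Camera called 12 lists, and 5 of them also with an estimated correlation. All 33 proliferation genes rose (33 adjusted over the list alone, median 0.93, adjusted p = 2.95e-44), including the cyclin gene Ccnd1 (1.48) and the replication genes Mcm7 (1.15) and Mcm5 (1.03). In the ER stress and amino acid list 21 of 22 fell (21 adjusted over the list alone, median -0.84, adjusted p = 3.02e-26), with Ddit3 at -1.71 and Sesn2 at -1.20. Of 28 interferon-stimulated genes 20 rose and 8 did not pass (21 adjusted over the list alone, median 0.33, adjusted p = 3.20e-13), with Gbp2 at 1.17 and Oasl2 at 0.92. All 6 megakaryocyte and platelet markers fell (6 adjusted over the list alone, median -1.42, adjusted p = 3.88e-08), with Itga2b at -1.65 and Pf4 at -1.49. Of 16 NRF2 targets 8 fell and 2 rose (8 and 3 adjusted over the list alone, adjusted p = 4.43e-05).

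The other 7 called lists had adjusted p over 0.05 with an estimated correlation. Of 23 adhesion genes 10 rose and 4 fell (11 and 4 adjusted over the list alone, adjusted p = 6.47e-05, and adjusted p = 0.0645 with an estimated correlation); Itgb7 rose by 1.75 and Pecam1 fell by 1.85. Of 13 neutrophil markers 7 fell and 6 did not pass (7 adjusted over the list alone, median -0.79, adjusted p = 0.000106, and adjusted p = 0.295 with an estimated correlation), with S100a8 at -1.24 and Ltf at -1.27. Without ApoE replicates 2 and 5 the median was -0.49 and 6 fell, and AS2 replicate 1 stood apart in the score of this list (-1.18, other AS2 arrays -0.584 to -0.404). Prtn3, chosen here after its values were seen, was 7.39 against 7.35 (adjusted p = 0.944). Of 8 osteoclast markers 3 rose (4 rose and 1 fell adjusted over the list alone, adjusted p = 0.0017, and adjusted p = 0.0509 with an estimated correlation): Acp5, Dcstamp and the collagen-degrading protease gene Ctsk (1.18). Of 16 fatty acid synthesis genes 6 rose and 2 fell (6 and 3 adjusted over the list alone, adjusted p = 0.0177, and adjusted p = 0.221 with an estimated correlation), with the desaturase genes Scd2 and Scd1 at 1.55 and 1.01. This call was also lost without ApoE replicates 2 and 5 (adjusted p = 0.0577). Of 22 scavenger receptors 8 fell and 5 rose (10 and 5 adjusted over the list alone, adjusted p = 0.0267, and adjusted p = 0.24 with an estimated correlation), with Cd163 at -1.29 and Clec7a at 1.39, and the call was lost without ApoE replicate 5 (adjusted p = 0.0724). The dendritic cell list (3 of 8 lower) and the endothelial list (2 of 7 lower, Kdr at -1.56 and Stab2) had adjusted p = 0.0242 and 0.0284. With an estimated correlation they had adjusted p = 0.149 and 0.0754, and they were lost without ApoE replicate 5 and AS2 replicate 5 (adjusted p = 0.0638 and 0.058). With rows of low mean left out, the scavenger receptor, dendritic cell and endothelial calls were lost (adjusted p = 0.104, 0.109 and 0.0559).

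In lists that were not called, single genes changed in both directions. Of 20 matrix genes 7 rose and 4 fell (7 and 7 adjusted over the list alone, adjusted p = 0.316), with the elastase gene Mmp12 at 1.63 and Tgfbi at 1.79. Of 25 lysosomal genes 6 rose and 13 fell (6 and 13 adjusted over the list alone, adjusted p = 0.0736), with Atp6v0d2 at 1.28 and Sqstm1 at -0.97. Of 15 LXR targets 4 rose and 5 fell (4 and 6 adjusted over the list alone, adjusted p = 0.316), with Abcg1 at 0.62 and Abca1 at -0.29. Of 18 PPAR targets 7 rose and 5 fell (7 and 5 adjusted over the list alone, adjusted p = 0.316), with Lpl at 1.28 and Fabp5 at -1.60. Of 25 chemokine genes 8 rose and 4 fell (9 and 6 adjusted over the list alone, adjusted p = 0.565), with Ccr2 and Ccl2 at 1.99 and 1.82. Of 25 immediate early genes 9 rose and 6 fell (10 and 6 adjusted over the list alone, adjusted p = 0.0763), with Egr2 at 1.47 and Egr1 at -0.73. The NF-kB list (6 and 6 of 23), complement list (4 and 4 of 14), MHC class II list (4 and 2 of 13, with the costimulatory gene Cd86 at -1.92), alternative activation list (5 and 5 of 18), glycolysis list (5 and 4 of 20), cholesterol synthesis list (1 and 1 of 21) and macrophage markers (4 and 3 of 10) had adjusted p from 0.247 to 0.97. In the same order, 6 and 8, 4 and 4, 4 and 2, 6 and 7, 7 and 5, 1 and 1, and 5 and 3 genes passed adjusted over the list alone. Without ApoE replicates 2 and 5 the MHC class II list was called (8 higher and 2 lower, adjusted p = 0.00713, and adjusted p = 0.226 with an estimated correlation), as was the lysosome list (adjusted p = 0.043, and adjusted p = 0.143 with an estimated correlation). B cell, T and NK cell, erythroid, mast cell and stromal markers had adjusted p from 0.176 to 0.808. The cholesterol synthesis, LXR, PPAR, NF-kB, complement and matrix lists had a median, mean and test that differed in sign.

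Of the 126 small RNA rows, 34 rose and 1 fell, with a median of 0.18 log2 units. Without ApoE replicates 2 and 5, 3513 rows changed rather than 3857.

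**Figure D4:**
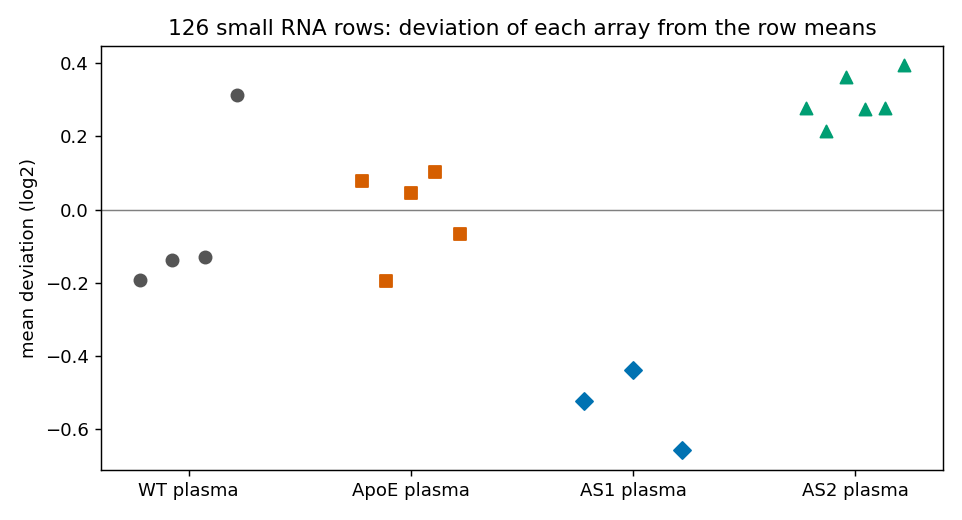
Mean deviation of 126 small RNA rows from their means over all 18 arrays, in log2 units, for each array by plasma. The AS1 arrays lay between -0.66 and -0.44 and the AS2 arrays between 0.21 and 0.40; WT replicate 4, at 0.31, lay above the other WT arrays.

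AS2 and AS1 plasma were also compared with each other, which tests whether expression differed between the arrays of these plasmas. Differences of genotype, plasma sample and culture cannot be told apart here, as the labels do not say what the replicates were. Of 24705 rows, 2847 were higher and 2620 lower with AS2 plasma, and 521 differed at least 2-fold. Pcdh7, Plau and Slc5a3 were higher by 2.99, 2.98 and 2.86 log2 units, and Fcrls, Retnlg and Marco were lower by values of -3.72, -3.20 and -3.19. All 13 neutrophil and all 6 megakaryocyte markers were lower with AS2 plasma, with medians of -2.17 and -1.83. The neutrophil list had camera adjusted p = 2.29e-15 and adjusted p = 0.0528 with an estimated correlation, and the megakaryocyte list 5.23e-08 and 0.0209. Of 33 proliferation genes 29 were higher, with a median of 0.66.

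Against WT plasma, 1196 rows were higher and 1147 lower with AS1 plasma. Ccna2, Cxcr2 and F5 rose by 2.85, 2.74 and 2.72, and Id3, Cd300e and Cbr2 fell by 2.73, 2.60 and 2.05. With AS2 plasma 2137 rows were higher and 2272 lower than with WT plasma. Prc1, Anln and Ccna2 rose by 3.49, 3.37 and 3.36, and Cd300e, Marco and Clec4n fell by 3.78, 3.65 and 3.56.

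Many genes that differed between ApoE and WT plasma differed the other way with AS1 or AS2 plasma. Of 2111 rows that rose with ApoE plasma, 1195 fell with AS1 and 924 with AS2 plasma, where independent lists would share 185.9 and 169.3. Of 2066 rows that fell, 1008 rose with AS1 and 701 with AS2 plasma (160.0 and 156.9 for independent lists). Of the same rising rows, 126 rose again with AS1 and 309 with AS2 plasma (163.5 and 160.3 for independent lists). Of the falling rows, 41 and 153 fell again (181.9 and 165.7). The ApoE arrays enter both comparisons with opposite signs, which independent lists ignore. Signs were opposite in 66.13% of rows for AS1 and 63.99% for AS2, against means of 63.1% and 66.1% in simulated unchanged groups. Across rows, the fold changes of ApoE against WT and AS1 against ApoE correlated at r = -0.545 against a mean of -0.396 in simulated unchanged groups, with a covariance of -0.0406 against -0.00402. With the ApoE arrays divided in 2 parts, the mean r was -0.45. For AS2 the correlation was -0.316, weaker than the simulated mean of -0.485, the covariance -0.022 against -0.00397, and the mean r of divided arrays -0.23. Both covariances had a permutation p = 0.0099 over the simulated sets, the smallest that 100 draws can give. Those sets held no group differences at all. A shift common to all ApoE arrays, whatever its source, lowers the covariance and the r of divided arrays by itself. Neither therefore shows that AS1 or AS2 plasma reversed the ApoE changes. Both correlations lay within the simulated intervals (-0.691 to -0.0735 for AS1 and -0.722 to -0.166 for AS2), so r does not show a reversal either.

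Among rows called with both AS1 and AS2 plasma against ApoE, some changed in the same direction and others in opposite directions. In both comparisons 508 rows rose and 713 fell, where independent lists would share 145.3 and 174.4. Another 323 rows rose with AS1 and fell with AS2 plasma and 215 did the reverse (153.4 and 165.2 for independent lists). Independent lists ignore the shared ApoE arrays. The sign was the same in 58.58% of rows, against a mean of 64.9% in simulated unchanged groups. Over all rows, agreement in sign thus did not exceed that mean. The correlation across rows was r = 0.143, against a mean of 0.45 in simulated unchanged groups that share the ApoE arrays. The covariance was 0.00979 against 0.00402 (permutation p = 0.0099), and r averaged 0.072 with the ApoE arrays divided, from -0.071 to 0.22. This covariance difference did not hold up in every fit. The permutation p was 0.277 without ApoE replicate 1, 0.0792 without ApoE replicate 2, 0.0594 without ApoE replicate 3 and 0.178 without ApoE replicate 4. It was 0.109 without AS1 replicate 2 and 0.0594 without WT replicate 3 in the same permutation test. With the replicate number as a block the permutation p was 0.119. Neither independent lists nor the simulated sets, which held no group differences, allow for a shift common to all ApoE arrays. Such a shift moves a row the same way in both comparisons. The shared counts and the covariance therefore do not show a response common to AS1 and AS2 plasma.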

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

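The tests on ApoE replicate 5 as a wrongly labelled array or as plasma mixed with AS1 plasma, on small RNA recovery and on the share of macrophages were chosen only after the results were seen.

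Among 468 sets of 4, 5 or 6 array values for 126 genes and 30 lists in the WT, ApoE and AS2 groups (AS1, with 3 arrays, was not tested), 34 had 1 array far from the rest of its group, where chance gives about 1 in 20, or 23.4. ApoE replicate 5 stood apart in Aif1 (7.03), Clec7a (9.37), Hmgcs1 (7.47), Kdr (5.55), Rai14 (6.38) and the endothelial list score (0.0814). ApoE replicate 2 stood apart in Cbr2 (5.27), Nqo1 (4.88), Ptchd1 (5.74), Tpx2 (7.43) and the interferon list score (-0.412), and ApoE replicate 3 in Vegfa (10.4). WT replicate 2 stood apart in Dcstamp (5.24), Fcgr1 (10.7), Stab2 (5.72) and the scores of the immediate early (-0.0766) and proliferation lists (-1.34), and WT replicate 1 in Bhlhe41 (6.89). AS2 replicate 1 stood apart in Cxcr2 (5.58), Il1b (4.1), Lcn2 (9.92), Ltf (8.38), Ngp (9.5) and Retnlg (5.67), and in the scores of the adhesion (-0.0729), neutrophil (-1.18), osteoclast (0.12) and stromal lists (0.0102). AS2 replicate 4 stood apart in Anln (8.78), Il10 (5.15), Oasl2 (8.24) and Plin2 (12.9), AS2 replicate 2 in Cd86 (7.33) and AS2 replicate 3 in Asns (8.6).

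In 538 rows AS1 and AS2 plasma differed from ApoE plasma in opposite directions. That all of them also differed between AS2 and AS1 follows from how they were chosen. Of the 723 rows without a listed gene, 149 differed between ApoE and WT, 147 between AS1 and ApoE and 142 between AS2 and ApoE plasma.

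ApoE replicate 5 lay at 0.374 ± 0.041 (jackknife SE) on a line from the other ApoE arrays (0) to the AS1 arrays (1), and at 0.229 on the like line to the WT arrays. This argues against an AS1 array under a wrong label, which would lie near 1. Its linear positions over rows higher and lower in AS1 differed by -0.191 ± 0.027. That would go against RNA mixed with AS1 RNA only if array values scaled with RNA amount, which was not tested, so mixed RNA stays undecided. The bound of this test was first written for RNA and plasma together and narrowed to RNA afterwards, since plasma need not act linearly. Mixed plasma remains a candidate explanation, with a position of 0.323 ± 0.065 over rows that set AS1 apart from every other group. Ordinary spread stays open too: the next ApoE array lay at 0.163 ± 0.03, under the bound of 0.2 set beforehand, but 4 arrays are too few to bound that spread, so the bound was wrong.

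Of 126 small RNA rows, 50 were lower and 1 higher in AS1 than in ApoE arrays, and 34 were higher and 1 lower in AS2, with a median difference of 0.57 log2 units between AS2 and AS1 over all 126. Recovery or labelling of small RNA may account for this but stays undecided: the WT arrays ranged over 0.505 log2 units, against a difference of -0.534 between AS1 and ApoE, but over 0.0606 without WT replicate 4. The 18 measured genes that are named Snhg or Gas5, hosts of small nucleolar RNAs, had a median difference of 0.221 ± 0.13 (bootstrap SD) between AS2 and AS1. This leaves another level of the host genes undecided, and host genes of other names were not examined. Of the 18, those past the threshold were higher in AS2, among them Snhg6 (1.1), Snhg1 (0.995) and Gas5 (0.657). Those that were lower, Snhg9 (-0.398), Snhg20 (-0.299), Snhg10 (-0.221) and Snhg14 (-0.0253), did not pass. An effect of the plasma stays open and was not tested.

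Of 13 neutrophil markers, 13 were higher in AS1 and 7 lower in AS2 than in ApoE arrays, with adjusted p = 0.0652 and 0.295 for the list with an estimated correlation. Granulocytic cells of 1 kind that carry both early and late genes would, if left in the culture, move these genes together. In AS1 the early and late genes both rose, with medians of 1.8 ± 0.22 and 1.27 ± 0.17 (bootstrap SD over genes). Such cells therefore stay open for the rise in AS1. In AS2, however, 4 early granule genes (Elane, Mpo and Prtn3 among them) had a median of -0.0589 ± 0.058 (bootstrap SD over genes, not arrays). The 6 late genes (S100a8, Ngp and Ltf among them) had -1.21. Cells that carry late genes alone stay open for the fall in AS2, and cells of 2 kinds or stages may still be present. A lower share of macrophages in AS1 stays undecided at a macrophage marker median of 0.338 ± 0.17 (bootstrap SD): a first test on 19 markers of other cells was void, as they lay at a median level of 3.9 against 4.37 for all rows. The bound for the macrophage test was then raised from 2 to 3 SD after its value was seen, because the value lay close to 2 SD.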

How the results depend on the processing

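The fit without ApoE replicates 2 and 5 was chosen only after the results were seen. Counts of rows changed stayed within 1.5 times the reported ones in every alternative run. Leaving out each array gave 3571 to 4348 rows for ApoE against WT, 3045 to 4429 for AS1 against ApoE and 3493 to 3927 for AS2 against ApoE. Without ApoE replicates 2 and 5 the counts were 4069, 4398 and 3513, the PPAR list was called for ApoE against WT (adjusted p = 0.0476) and the stromal list for AS1 (0.0172), and the dendritic cell list was lost for AS2 (0.0792). With an estimated correlation, the PPAR and stromal lists were not called in this fit (adjusted p = 0.155 and 0.0575). Calls were also gained in other alternatives. Of 26 settings per list, the stromal list for AS1 passed in 6, and the immediate early and lysosome lists for AS2 in 4 each. Camera with an estimated correlation called 8, 6 and 5 lists in these comparisons, and fry called 20 for AS2 against ApoE. Fry tests whether a list's genes move one way on balance and does not compare them with other genes, so its count answers another question. The correlation between the AS1 and AS2 changes ranged from 0.108 without AS1 replicate 2 to 0.231 without ApoE replicate 5. Of 7319 alternative values of named genes, 7172 kept their side of the threshold, 116 fell short of it and 31 passed it. With the reported or the alternative value past the threshold, 0 reversed direction. Any reversals where neither value passed were counted among the 7172. The cause of the losses was not tested.

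The replicate numbers did not pair the arrays: of 22 same-numbered pairs, 4 had correlated deviations over 0.1 (from -0.207 to 0.133), and 4 correlated best with their own number. With the replicate number as a block, 3945, 3748 and 3475 rows and 15, 19 and 12 lists were called, and the correlation of the AS1 and AS2 changes was 0.144 (permutation p = 0.119). The glycolysis list was lost for AS1 under the block (adjusted p = 0.0558). A filter on rows of low mean ended 11 list calls, most of them of marker lists or scavenger receptors. Arrays of equal distributions do not show signal over background, so the limit for dim genes is unknown.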

Other observations

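Against WT plasma, proliferation genes were higher with both double-knockout plasmas: 29 of 33 rose with AS1 plasma (31 adjusted over the list alone, median 1.34 log2 units) and 33 of 33 with AS2 plasma (33 adjusted over the list alone, median 2.01). Neutrophil markers had 12 of 13 higher with AS1 plasma (13 adjusted over the list alone, median 1.67), whereas 6 were lower and 1 higher with AS2 plasma (8 and 1 adjusted over the list alone, median -0.60). The neutrophil list was not called for AS2 (camera adjusted p = 0.0512), and for AS1 it had adjusted p = 6e-19 and adjusted p = 0.0355 with an estimated correlation. Of 6 megakaryocyte and platelet markers, 5 rose and 1 fell with AS1 plasma (5 and 1 adjusted over the list alone, median 1.43), and 1 fell with AS2 plasma (1 adjusted over the list alone, median -0.18, list not called, adjusted p = 0.0961). Of 22 ER stress and amino acid genes, 4 were higher with AS1 plasma than with WT plasma (median 0.168). With AS2 plasma 9 were higher and 2 lower (median 0.218). Camera called this list for both (adjusted p = 0.00418 and 0.000624), but not with an estimated correlation (adjusted p = 0.398 and 0.347).

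All tests of other groupings of the arrays were planned. For rows changed, the real split alone reached its count in each comparison: 1 of 100 splits for ApoE against WT (4177, highest other 3563), 1 of 56 for AS1 against ApoE (4088, highest other 2082) and 1 of 100 for AS2 against ApoE (3857, highest other 2025). The same held for AS2 against AS1 in 1 of 84 (5467, highest other 35), AS1 against WT in 1 of 35 (2343, highest other 1019) and AS2 against WT in 1 of 100 (4409, highest other 427). Where 100 splits are given, they were a sample of all splits. Counts this large were thus rare among other groupings of these arrays. Since replicates may be technical, such splits cannot exclude a chance difference between cultures or plasma samples. For gene lists, 1 of 56 splits for AS1 against ApoE (21, highest other 19) and 2 of 100 for AS2 against ApoE (12, highest other 13) gave as many or more, the real split included. Such counts were rare among the splits, which does not exclude chance. In these splits p-values were adjusted within 1 comparison, which gives 21 lists for AS1 rather than 20. For ApoE against WT, 8 of 100 splits gave as many lists (15, highest other 17), and chance was not excluded.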
